A study of Sus scrofa with 3 samples.

How the data were processed

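Single-cell 3′ RNA libraries were made with the 10x Chromium v3 kit, per the labels, from pig cells in 3 groups with 1 library each: fetal fibroblasts as the somatic control, embryonic stem cells (ESCs) grown on feeder cells, and ESCs grown without feeders. Both ESC cultures received a medium with 20 ng/mL FGF2, 5 ng/mL activin A, 1.5 µM CH and 2.5 µM IWR-1 (CH and IWR-1 act on WNT signalling), and 10 µM Y-27632, a ROCK inhibitor, around passaging. The feeder-free cells also received 250 nM LDN-193189, an inhibitor of BMP type I receptors, and were used after more than 3 passages off feeders. Feeder removal and LDN-193189 therefore come together in these libraries. The labels describe a magnetic sort for the surface antigen SSEA4 to remove feeder and differentiated cells before extraction; they do not state plainly whether it was applied to the suspensions loaded for single-cell capture. The species of the feeder cells is not stated.

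The authors deposited raw UMI counts per gene and barcode, with no cell calling: each matrix lists 27352 genes and 6794880 barcodes. The feature files deposited with them hold gene names and no measurement (unit other), and 26851 of the 27352 names were found in the reference gene table of Sscrofa11.1, from which chromosome positions were taken. Per the submitters' processing notes, the counts came from Cell Ranger 5.0.0 on Sscrofa11.1, whereas the matrix headers name Cell Ranger 4. The 13 mitochondrially encoded genes are listed with 0 UMIs in all 3 files, so no mitochondrial filter could act.

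Gene lists, comparisons, filters and the rules for naming genes were fixed before the data were examined. Cells were called by the order-of-magnitude rule: a barcode was kept with at least 10% of the 99th percentile of UMIs among the top 3000 barcodes, which gave thresholds of 4091 UMIs for fibroblasts, 7366 for feeder ESCs and 4931 for feeder-free ESCs. At least 500 genes detected and at most 20% mitochondrial UMIs were also required. Doublets were scored per library with Scrublet (scanpy 1.11.5, expected rate 0.06) and kept. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.

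UMI counts were summed over the cells of a library and expressed as CPM over all genes. With 1 library per group there is no replicate, so no test, p-value or standard error was computed, and cells were not treated as replicates. CPM values carry exact Poisson 95% intervals, ratios exact conditional binomial 95% intervals and shares of cells exact Clopper-Pearson 95% intervals; all cover counting error only. A gene was measured in a comparison with at least 5 CPM in either library. It was called higher or lower when the ratio was at least 1.5-fold and the interval left out 1. A library with 0 counts was set to a floor of 3 counts over the library, and such ratios are lower bounds.

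For 29 gene lists and the ribosomal protein genes, the median log2 ratio of measured members was computed with an order-statistic 95% interval (given from 6 members upward) and with its percentile among 10000 random lists of the same size matched on mean expression. Genes were named by rule: in each comparison the 12 highest and 12 lowest ratios among genes with a symbol, at least 25 CPM in the higher library and an interval leaving out 1 (for ESCs against fibroblasts, ranked by the smaller of the ratios in both ESC libraries), without ribosomal or mitochondrial genes. Up to 4 members with the largest ratios were named per list, and 16 genes were always reported. Ribosomal protein genes were taken by symbol, which also took in RPS19BP1 and RPL7L1. Other genes in the text were picked from the lists or clusters after their values were seen. XIST was among the 16 but has no entry under that name in the files.

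Each library was clustered alone: log of counts per 10000 plus 1, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. Clusters were named from 13 marker classes. A class name needed at least 3 of its markers at 20 CPM or more and at least 2-fold above the rest of the library. It also needed a marker of that class, or a member of the matching gene list, among the cluster's 10 leading genes. Cluster 1 of feeder ESCs met this through PRRX1, a member of the fibroblast and mesenchyme list, with no fibroblast marker among those 10. Without such a class, a cluster was named pluripotent-like or fibroblast-like when at least 3 of those markers reached 20 CPM and its leading genes did not hold more markers of other classes; the remaining clusters stayed unnamed. The 3 libraries were also clustered together. The share of cells with a UMI was computed for 15 markers after thinning every cell to 2000 UMIs; no cell was left out by this thinning.

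The ratio calls were tested on simulated data made from the summed profiles of all 27352 genes. At each of 2-fold, 3-fold, 4-fold and 8-fold, 50 genes were changed, some raised and some lowered. In the right direction, 50 of 50 were called in each case, except 49 of 50 at 3-fold for feeder-free ESCs against fibroblasts. No call was made among 9752, 9087 and 9100 unchanged genes, and 95.25%, 94.87% and 94.87% of their intervals held the true ratio. Without replicate libraries, variation between libraries could not be estimated for this simulation. The simulated calls and intervals therefore speak for counting error alone. They cannot show how often a call would be false between replicate libraries. A list of 12 genes raised 4-fold gave medians of 2.01, 1.93 and 1.97 on the log2 scale, and 12 unchanged genes gave 0.01, -0.06 and -0.01.

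Alternatives covered TMM factors (0.838, 1.12 and 1.06 for fibroblasts, feeder and feeder-free ESCs), totals without ribosomal genes, the mean of each cell's CPM, thinning to 2000 UMIs, other cell calls (10000 expected cells or at least 1000 UMIs), doublets left out, subtraction of 10% free RNA estimated from barcodes with at most 100 UMIs, expression limits of 20 CPM or none, other cluster settings and other thinning depths. After the data were seen, 3 more were added: leaving out the fibroblast-like cluster of the feeder ESCs, keeping the pluripotent-like clusters of the ESC libraries alone, and keeping cells with at least 15000 UMIs.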

Results

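Single-cell transcriptomes of pig cells were compared between fetal fibroblasts, ESCs on feeder cells, and ESCs kept without feeders under the BMP receptor inhibitor LDN-193189, with 1 library in each of the 3 groups. The files held 61821467 UMIs for fibroblasts, 47437648 for feeder ESCs and 60684918 for feeder-free ESCs. After cell calling, 3209 fibroblasts, 1387 feeder ESCs and 2260 feeder-free ESCs remained, with 95.4%, 90.2% and 84.4% of the UMIs of their files. The median cell had 17419, 29170 and 20851 UMIs and 3978, 5757 and 4727 genes in the same order. Ribosomal protein genes took 26.2%, 24.5% and 25.1% of UMIs. Scrublet called 1, 13 and 8 doublets, which were kept. No difference below has a replicate check, because each group is 1 library. Intervals of CPM values, ratios and shares of cells cover counting error alone. Those of list medians reflect the spread between member genes. None covers variation between libraries.

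The ESC libraries differed in makeup. In feeder ESCs, clusters 2, 4 and 5 were named pluripotent-like, with at least 3 pluripotency markers detected and no more listed markers of other classes than of pluripotency among their 10 leading genes, and held 674 of 1387 cells (48.6%, 95% interval 45.9 to 51.3). Cluster 1 was fibroblast-like and held 412 cells (29.7%, 27.3 to 32.2) with 11.9% of the library's UMIs and a median of 11413 UMIs per cell. It carried PRRX1 at 932 CPM, CRABP1 at 2245 CPM and CRYAB at 882 CPM, against 9.09, 22.6 and 5.28 CPM in the other feeder ESCs. Among the pluripotent-like clusters, cluster 5 (98 cells) was led by contractile and matrix genes outside the marker lists, with TAGLN at 651 CPM against 298 CPM and COL6A2 at 63.98 against 31.0 CPM. A cluster of 31 cells (2.24%, 1.52 to 3.16) was named neuroectoderm-like, with SIX6 at 118 CPM, but this class held 0% of cells in 4 of 5 other clustering settings. Clusters 3 and 6 stayed unnamed, at 19.5% of cells. Cluster 3 combined POU5F1 with APOA1, KRT7 and SMAD7. Cluster 6 held 9 of the 13 called doublets and combined POU5F1 with genes that were high in cluster 1. PCDH19 was at 71.2 CPM in cluster 6 and 209 CPM in cluster 1, and NPPC at 60.2 and 138 CPM. This library was prepared from a culture that contained feeders, and the labels leave open whether the SSEA4 sort preceded its capture.

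Feeder-free ESCs held 1910 pluripotent-like cells of 2260 (84.5%, 83.0 to 86.0), in clusters 1, 2, 3, 4 and 6. Cluster 5, with 298 cells (13.2%, 11.8 to 14.7), was amnion or trophectoderm-like: GATA3 reached 145 CPM against 6.55 CPM in the rest of the library, TFAP2A 98.96 against 4.89, WNT6 86.8 against 6.10 and PLET1 168 against 4.71. These genes mark extraembryonic epithelium around implantation. A further 52 cells (2.30%) stayed unnamed, with CXCL14 at 1001 CPM. All 7 clusters of the control library were fibroblast-like, so 100% of its cells were (99.9 to 100). The class names were rebuilt from marker genes and the classes rest on different clusters in the ESC libraries, so their shares compare only loosely. The unnamed share was 0% in fibroblasts. Ratios in pluripotent-like clusters alone also rest on unlike selections of cells. Feeder ESC cluster 3, with 23.2% of the library's UMIs, is left out. In joint clustering, 215 of its 216 cells grouped with clusters 2, 4 and 5. Feeder-free clusters 4 and 6 are kept, although most of their cells (355 of 408 and 67 of 90) grouped with cluster 5. Other clustering settings gave 43.8% to 64.6% pluripotent-like and 28.4% to 29.99% fibroblast-like cells in feeder ESCs, 71.0% to 82.3% pluripotent-like cells in feeder-free ESCs, and as little as 63.4% named cells in fibroblasts. When the 3 libraries were clustered together, each of 9 clusters drew at least 95.25% of its cells from a single library.

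**Figure D1:**
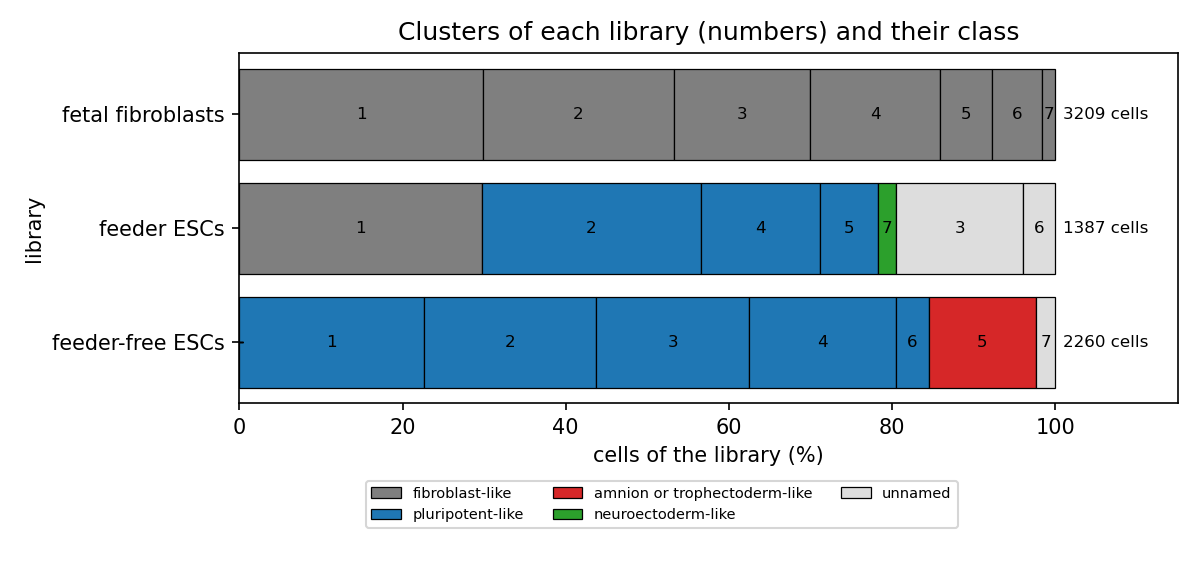
Share of cells (percent, x axis) in each numbered cluster, colored by marker-named class, as stacked bars for the 3 libraries (y axis). There is 1 library per group, and no intervals are drawn. Fibroblast-like cells made up 29.7% of the feeder ESC library, and amnion or trophectoderm-like cells 13.2% of the feeder-free ESC library.

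The comparison of feeder-free with feeder ESCs asked how the cells differ once feeders are removed and BMP receptors are inhibited. Core pluripotency genes lay at similar levels: POU5F1 was at 1296 CPM (1286 to 1307) on feeders and 1360 CPM (1350 to 1370) without, SOX2 at 224 and 266 CPM, and SALL4 at 86.5 and 73.7 CPM. These ratios stayed under 1.5-fold in every setting tried, but the sign for POU5F1 and SALL4 turned under other weightings or selections of the cells. Genes of amnion and trophectoderm were higher in feeder-free ESCs, with GATA3 at 0.794 CPM (0.550 to 1.11) on feeders and 25.01 CPM (23.7 to 26.4) without. Genes of primed pluripotency, the state of the epiblast before gastrulation, were lower, with OTX2 at 59.8 and 30.8 CPM and ZIC2 at 77.02 and 34.5 CPM. Mesenchymal genes were far lower, with COL3A1 at 35.8 CPM (34.0 to 37.6) on feeders and 0.293 CPM (0.164 to 0.483) without, and this difference lay mostly in the fibroblast-like cluster of the feeder library.

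**Figure D2:**
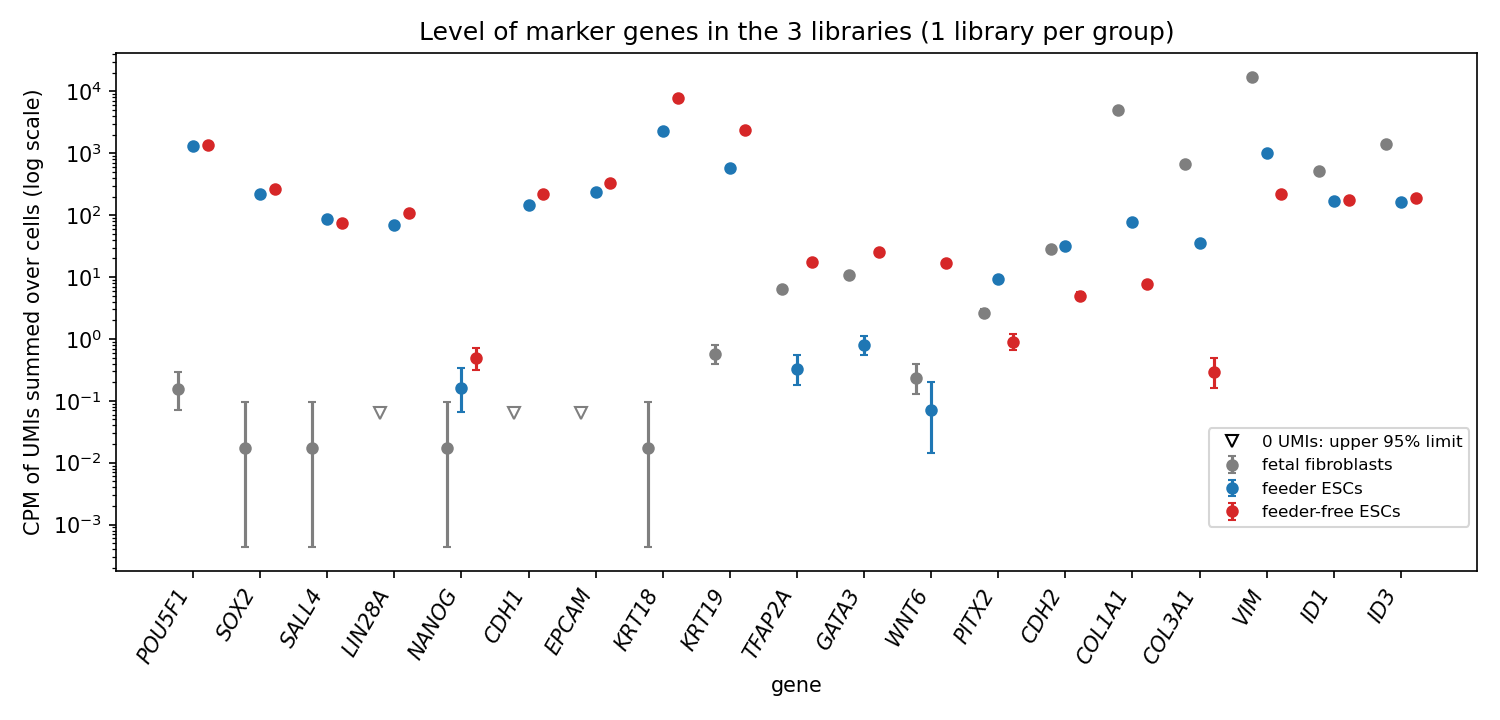
CPM of summed UMIs (log scale, y axis) for marker genes (x axis) in fetal fibroblasts, feeder ESCs and feeder-free ESCs, 1 library each, with exact Poisson 95% intervals and open triangles at the upper limit for 0 UMIs. POU5F1 is at 1296 and 1360 CPM in the ESC libraries and 0.153 CPM in fibroblasts, while GATA3 is at 0.794 and 25.01 CPM in the ESC libraries.

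Among 10284 measured genes, 9.74% were at least 1.5-fold higher and 13.9% at least 1.5-fold lower in feeder-free ESCs, with a median log2 ratio of -0.10; under TMM scaling the shares were 11.5% and 10.9%. With the pluripotent-like clusters alone, 7.11% were higher and 13.8% lower. The highest ratio was that of FXYD4, a regulator of the sodium pump on chromosome 14 (61633355 to 61637733), at 0.140 CPM on feeders and 45.4 CPM without (log2 8.34, 7.21 to 9.79). PLET1, an epithelial surface protein of the placenta, followed at 0.210 and 26.5 CPM. CYP1A1, a target of the aryl hydrocarbon receptor, stood at 0.304 and 36.1 CPM. Epithelial genes SFN (15.7 and 472 CPM), TACSTD2 (10.2 and 202 CPM) and FXYD3 (3.50 and 86.6 CPM) were also among the 12 highest, with GATA3, FAM111A, AIF1, GLRX, HENMT1 and CXCL13. All 12 were also higher when only pluripotent-like clusters were compared, at log2 2.59 for GLRX to 7.50 for CYP1A1, but FXYD4, PLET1, GATA3 and GLRX lead cluster 5, and their excess over feeder ESCs there was 2.40% to 5.01% of their level in cluster 5, so free RNA of that cluster is not excluded for them. GATA3 rested there on 1 UMI in feeder ESCs (log2 6.55, 4.05 to 11.86), and FXYD4 on 0 UMIs, for a ratio of at least 71.2-fold. Feeder-free clusters 4 and 6 grouped mostly with cluster 5 in joint clustering. Without them, the log2 ratios of the 12 genes ran from 1.87 for GLRX to 6.92 for CYP1A1. FXYD3 fell from 75.5 to 25.7 CPM, FAM111A from 21.0 to 7.28 and HENMT1 from 79.7 to 37.0. The excess became 0.87% to 2.64% for FXYD4, PLET1, GATA3 and GLRX, 8.22% for FAM111A and 9.65% for SFN.

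The 12 lowest ratios in feeder-free ESCs belonged to PRRX1, NFIX, GNG11, COL3A1, GSTM3, MCTS1, GPX1, CDH11, CRABP1, NFKBIA, ZEB2 and CRYAB. PRRX1, a transcription factor of limb and craniofacial mesenchyme on chromosome 4 (80427682 to 80502689), was at 119 CPM on feeders and 0.195 CPM without (log2 -9.25, -10.31 to -8.37). With pluripotent-like clusters alone it was at 1.70 and 0.207 CPM (log2 -3.04). The direction turned there for CRABP1, a retinoic acid binding protein, from -4.73 to 0.67, and for CRYAB, a small heat shock protein, from -4.66 to 0.93. In the fibroblast-like cluster itself, 379 of 1924 genes (19.7%, 17.9 to 21.6) that reached 50 CPM in all other ESC clusters lay under 10% of their lowest level there, against at most 3.22% in the clusters of the fibroblast library. RPL29, RPS15A, SLC25A6 and MIF were among them, although only 4 of 82 genes with ribosomal protein symbols were (the others RPL7L1 and RPS19BP1).

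Lists are given for feeder-free ESCs over feeder ESCs. Of 12 core pluripotency genes, 1 was higher (LIN28A, 69.4 and 110 CPM) and 0 were lower, with a median log2 ratio of -0.06 (-0.34 to 0.25) that turned to 0.11 under TMM. NANOG was detected at 0.164 and 0.488 CPM, too few UMIs for a firm ratio (log2 1.58, 0.33 to 3.03). Of 13 primed pluripotency genes, 0 were higher and 9 lower, at a median of -0.96 (-1.71 to -0.34), at percentile 0 among 10000 random lists matched on expression. CDH2 was at 31.6 and 5.00 CPM, POU3F1 at 8.01 and 2.56 CPM, SOX4 at 199 and 60.7 CPM, and SOX11 at 180 and 73.0 CPM. The primed median was -0.83 in pluripotent-like clusters alone, with 10 of 13 lower. Of 4 naive pluripotency genes, 2 were higher and 1 lower (median 0.47): DPPA3 was at 2.15 and 6.74 CPM and KLF5 at 6.14 and 10.4 CPM. KLF4 was lower over all cells (log2 -0.79) but higher in the pluripotent-like clusters (1.20), where after thinning 0 of 3 naive genes were higher or lower. Thinning lowers the counts behind each ratio, which alone can cut the number of calls, here and in the lists below.

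Signalling targets split by pathway for feeder-free ESCs over feeder ESCs. Activin and Nodal target genes were lower in 5 of 7 and higher in 0, at a median of -1.88 (-4.03 to -0.19), although both media contained activin A at 5 ng/mL. PITX2 was at 9.25 and 0.898 CPM, NODAL at 17.3 and 4.71 CPM, SMAD7 at 40.8 and 8.01 CPM, and PMEPA1 at 146 and 8.92 CPM. The median was -0.83 in pluripotent-like clusters, with 3 of 5 lower. After thinning there it was -0.91, with an interval that reached 0 (-1.415 to 0.012) and 3 of 6 lower. NODAL also counts as a primed gene and SMAD7 as a BMP target. BMP target genes were mixed, 5 higher and 2 lower of 9 (median 1.26, -1.29 to 4.98). The immediate SMAD targets ID1 (171 and 178 CPM) and ID3 (161 and 190 CPM) lay within 1.5-fold, ID2 was higher (7.89 and 18.9 CPM) and ID4 lower (23.0 and 9.39 CPM), while GATA2 and DLX5 (0.257 and 8.14 CPM) were higher. The median was -0.03 in pluripotent-like clusters, with 1 higher and 2 lower of 5. Among BMP ligands, receptors and SMADs, 2 were higher and 5 lower of 12 (median -0.24, and 0.13 in pluripotent-like clusters after thinning), with BMP4 at 2.17 and 13.3 CPM and BMP2 at 15.0 and 2.01 CPM. Within feeder-free ESCs, BMP4 was at 67.4 CPM in cluster 5 against 5.02 CPM in the rest of the library. It was at 130 CPM in unnamed cluster 7. WNT target genes had 1 higher and 3 lower of 7 (median -0.38, -0.02 under TMM and -0.71 in pluripotent-like clusters), including MYC at 34.6 and 10.3 CPM. FGF and ERK target genes had 1 higher and 6 lower of 15 (median -0.33), with SPRY2 at 61.7 and 17.7 CPM, DUSP6 at 102 and 48.8 CPM and IER3 at 0.748 and 6.00 CPM.

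Lineage lists for feeder-free ESCs over feeder ESCs were led by amnion and trophectoderm genes, higher in 8 of 9 and lower in 0, at a median of 2.35 (1.24 to 5.73) and percentile 100 among random matched lists. WNT6 was at 0.0701 and 16.8 CPM, TFAP2A at 0.327 and 17.4 CPM, KRT19 at 582 and 2352 CPM, TFAP2C at 6.80 and 29.6 CPM and GABRP at 6.49 and 33.1 CPM. With pluripotent-like clusters alone, 4 of the 5 genes still measured were higher and 0 lower, at a median of 1.58; without feeder-free clusters 4 and 6, which grouped mostly with cluster 5 when the libraries were clustered together, 3 of 5 were higher at a median of 0.80. In the pluripotent-like clusters of feeder-free ESCs, GATA2, GATA3, TFAP2A and WNT6 stood at 2.55% to 4.72% of their level in cluster 5, and barcodes with at most 100 UMIs carried GATA3 at 16.1 CPM. Primordial germ cell genes were higher in 3 of 5 and lower in 0 (median 1.65), with PRDM1 at 1.68 and 9.31 CPM; in pluripotent-like clusters 2 were higher and 1 lower of 4 (median 0.96, and 0.84 after thinning). TFAP2C belongs to both lists, and GATA2 and GATA3 also count as BMP targets. Endoderm genes had 1 higher and 1 lower of 5 (median 0.12): FOXA2 was at 10.5 and 0.137 CPM and GATA6 at 4.30 and 23.1 CPM; the median was -0.39 in pluripotent-like clusters and 0.79 there after thinning, with 1 higher and 0 lower in both. Primitive streak and mesendoderm genes had 0 higher and 2 lower of 4 (median -0.45), with EOMES at 9.79 and 5.53 CPM; in pluripotent-like clusters 1 was higher and 1 lower of 3 (-0.44), and after thinning 1 was higher and 0 lower of 2 (0.55). Of 2 measured neuroectoderm genes, NES was lower (74.3 and 27.5 CPM) and MAP2 neither (median -0.53). Fibroblast and mesenchyme genes were lower in 13 of 14 (median -3.40, -6.60 to -1.09). The median was -1.04 without the fibroblast-like cluster, a setting that still holds feeder ESC cluster 6, and 0.10 in pluripotent-like clusters alone.

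**Figure D3:**
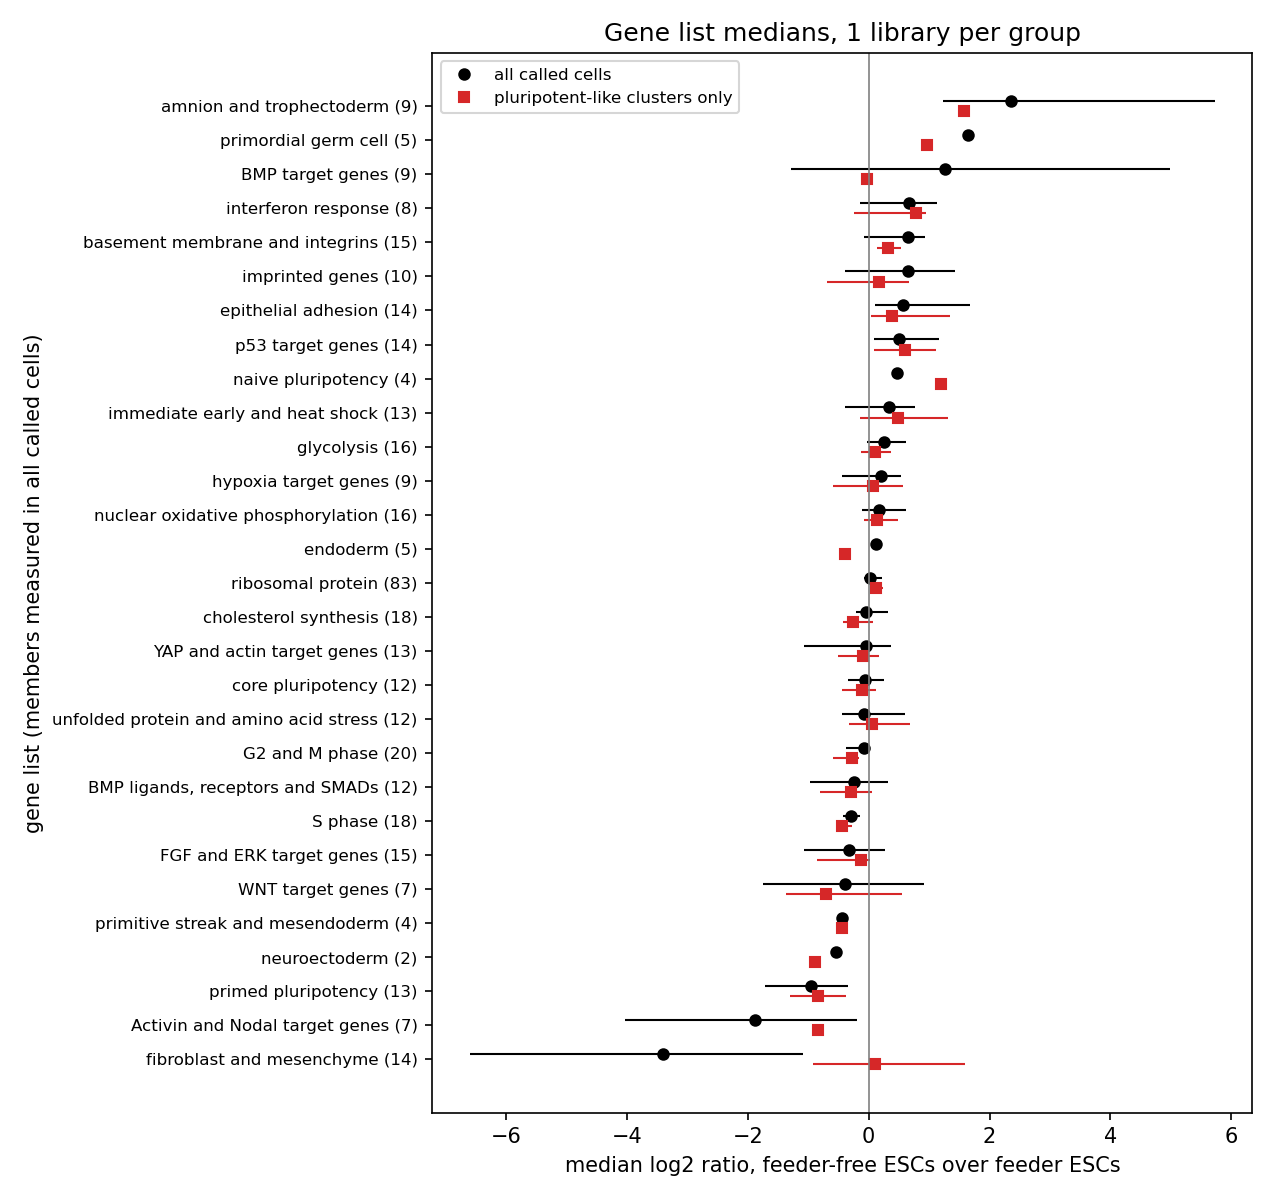
Median log2 ratio (x axis) of the measured members of each gene list (y axis) for feeder-free ESCs over feeder ESCs, 1 library per group. Values are shown for all called cells and for pluripotent-like clusters only, with order-statistic 95% intervals where at least 6 members were measured. Over all called cells the amnion and trophectoderm list lies at 2.35 and the fibroblast and mesenchyme list at -3.40.

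Epithelial and matrix genes also differed for feeder-free ESCs over feeder ESCs. Epithelial adhesion genes were higher in 6 of 14 and lower in 0 (median 0.56, 0.11 to 1.67), with KRT8 at 2390 and 7599 CPM, KRT18 at 2266 and 7874 CPM, and the tight junction gene CLDN4 at 68.2 and 301 CPM. The median was 0.39 in pluripotent-like clusters, with 4 higher. Basement membrane and integrin genes had 8 higher and 2 lower of 15 (median 0.65); the fibronectin receptor subunit ITGA5 was at 12.3 and 56.4 CPM and laminin LAMA5 at 46.1 and 102 CPM, against 133 and 39.8 CPM for FN1. The basement membrane median was 0.32 in pluripotent-like clusters, with 3 higher and 1 lower. YAP and actin target genes had 2 higher and 4 lower of 13 (median -0.04, and 0.04 under TMM), with ACTA2 at 294 and 16.0 CPM and ANKRD1 at 0.0934 and 6.76 CPM.

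Stress, growth and metabolic lists follow for feeder-free ESCs over feeder ESCs. Targets of p53 were higher in 6 of 14 and lower in 1 (median 0.51, 0.09 to 1.17), with CDKN1A at 79.6 and 182 CPM, MDM2 at 42.0 and 88.2 CPM and FAS at 3.01 and 10.2 CPM. BAX was the lower member (log2 -1.10) but was at 0.44 in pluripotent-like clusters, where 7 of 14 were higher. Interferon response genes were higher in 6 of 8 (median 0.66), with ISG15 at 34.2 and 66.5 CPM. In pluripotent-like clusters 5 of 7 were higher (median 0.78, -0.24 to 0.96). After thinning there, 1 of 7 was called higher (0.38, -0.04 to 1.08), with fewer counts behind each call. Imprinted genes had 6 higher and 1 lower of 10 (median 0.65, and 0.18 in pluripotent-like clusters), with MEST at 11.03 and 42.4 CPM. Within feeder-free ESCs, MEST was at 230 CPM in cluster 5 against 13.6 CPM in the rest of the library. Immediate early and heat shock genes had 4 higher and 2 lower of 13 (median 0.34); ATF3 was at 10.8 and 44.2 CPM, and JUN was lower over all cells (-1.40) but higher in pluripotent-like clusters (1.81). Unfolded protein and amino acid stress genes had 3 higher and 1 lower of 12 (median -0.07, and 0.05 in pluripotent-like clusters). Glycolysis genes had 4 higher and 0 lower of 16 (median 0.25, and 0.11 with 0 higher in pluripotent-like clusters), with SLC2A1 at 50.1 and 135 CPM, hypoxia target genes 1 higher and 1 lower of 9 (0.21), and nuclear oxidative phosphorylation genes 4 higher and 0 lower of 16 (0.17). Within feeder-free ESCs, SLC2A1 was at 534 CPM in cluster 5 against 73.5 CPM in the rest. Cholesterol synthesis genes had 1 higher and 2 lower of 18 (-0.04, and 0.04 under TMM).

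Cell cycle lists for feeder-free ESCs over feeder ESCs depended on which cells were counted. S phase genes had 0 higher and 2 lower of 18 (median -0.29), with UHRF1 at 45.9 and 19.8 CPM; this median turned to 0.059 when each cell weighed the same and to 0.028 after thinning, but was -0.43 in pluripotent-like clusters (0 higher and 3 lower of 17) and -0.44 there after thinning (0 and 6 of 18). G2 and M phase genes had 1 higher and 1 lower of 20 (-0.08, and 0.00 under TMM), with MKI67 at 59.1 and 44.3 CPM; the median was -0.27 in pluripotent-like clusters (0 higher and 6 lower) and -0.31 there after thinning (0 and 7). Ribosomal protein genes had 10 higher and 4 lower of 83 (0.03). Mitochondrially encoded genes had 0 UMIs and were not measured.

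Each ESC library was next set against the fibroblasts, which asks what separates pluripotent from somatic cells in these cultures. POU5F1 was at 0.153 CPM in fibroblasts, SOX2 at 0.0170 CPM, and UTF1 and LIN28A at 0 UMIs. Collagens and VIM ran the other way: COL1A2 was at 6648 CPM in fibroblasts, 48.8 CPM in feeder ESCs and 4.20 CPM in feeder-free ESCs, COL1A1 at 4937, 76.97 and 7.85 CPM, and VIM at 17370, 1013 and 223 CPM. Epithelial CDH1 and EPCAM had 0 UMIs in fibroblasts, so CDH1 was at least 2858-fold and 4247-fold higher in feeder and feeder-free ESCs.

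Among the 12 genes with the highest ratios in both ESC libraries were KRT18, SOX2, UTF1, POU5F1, ERAS, EPCAM, SPINT1, SALL4, DSP, CDH1, CLDN10 and CRB3. KRT18, a keratin of simple epithelia, was at 0.0170 CPM in fibroblasts (1 UMI) and 2266 and 7874 CPM in feeder and feeder-free ESCs. ERAS, an ESC-expressed RAS relative, was at 0.0848, 545 and 825 CPM. The 12 lowest were ASPN, TMEM119, AKR1CL1, MFAP4, FMOD, PAX1, TRIM25, PALMD, IFIT1, PRRX2, ADAM12 and ZBED2. ASPN, a small proteoglycan of connective tissue, was at 424 CPM in fibroblasts, 0.117 CPM in feeder ESCs and 0.0195 CPM in feeder-free ESCs. PRRX2, a mesenchymal homeobox factor, was at 1211, 1.87 and 0.527 CPM.

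Of 10993 genes measured for feeder ESCs over fetal fibroblasts, 45.6% were higher and 25.3% lower, at a median log2 ratio of 0.45; under TMM the median was -0.02 and the shares 32.7% and 34.8%. All 12 core pluripotency genes were higher (median 10.41, 8.35 to 13.05, 6 of them set by the floor), as were 10 of 13 primed genes with 1 lower (3.56), and 2 of 4 naive genes with 2 lower (0.94): ZFP42 was at 0.2204 and 109 CPM, KLF4 at 38.8 and 15.7 CPM. Epithelial adhesion genes were higher in 13 of 14 (9.60). Both cycle lists were higher, S phase in 17 of 18 (3.06) and G2 and M phase in 20 of 20 (2.92), with MCM2 at 4.27 and 107 CPM. Primordial germ cell genes were higher in 3 of 3 (4.48), endoderm in 3 of 3 (3.83), primitive streak and mesendoderm in 3 of 5 with 2 lower (3.72), FGF and ERK targets in 9 of 15 with 2 lower (1.92), and Activin and Nodal targets in 5 of 7 with 1 lower (1.82, but -1.14 in pluripotent-like clusters). Amnion and trophectoderm genes had 4 higher and 3 lower of 8 (0.51).

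The lists that were lower for feeder ESCs over fetal fibroblasts were led by interferon response genes, lower in 15 of 15 (median -5.02), and fibroblast and mesenchyme genes, lower in 18 of 20 (-4.68, and -7.60 in pluripotent-like clusters). IFIT3 was at 52.6 and 0.117 CPM and IFIT1 at 45.7 and 0.0701 CPM. YAP and actin targets were lower in 11 of 12 (-3.76), with ACTA2 at 8708 and 294 CPM, BMP targets in 11 of 12 (-3.18), with ID3 at 1429 and 161 CPM, and unfolded protein and amino acid stress genes in 11 of 13 (-2.14), with PSAT1 at 340 and 13.7 CPM. Neuroectoderm genes had 1 higher and 3 lower of 4 (-2.45), basement membrane and integrin genes 1 and 8 of 16 (-0.97), hypoxia targets 2 and 7 of 11 (-0.88), immediate early and heat shock genes 3 and 8 of 14 (-0.78), and WNT targets 3 and 4 of 8 (-0.65). Glycolysis had 4 higher and 6 lower of 16 (-0.40, and -0.83 under TMM), cholesterol synthesis 2 and 6 of 18 (-0.22), ribosomal protein genes 10 and 8 of 83 (-0.09, and -0.51 under TMM), p53 targets 7 and 5 of 14 (0.49), and nuclear oxidative phosphorylation 8 and 0 of 16 (0.57, and 0.15 under TMM). BMP ligands, receptors and SMADs had 5 higher and 3 lower of 14 (0.09, and -0.33 under TMM), and imprinted genes 4 and 4 of 11 (0.05, and -0.37 under TMM).

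For feeder-free ESCs over fetal fibroblasts, 42.6% of 10888 measured genes were higher and 26.1% lower, at a median of 0.35; under TMM the median was -0.03 and the shares 31.5% and 34.4%. Core pluripotency genes were higher in 11 of 11 (median 10.75, 6 set by the floor), epithelial adhesion genes in 14 of 14 (10.46), primordial germ cell genes in 5 of 5 (6.66), endoderm genes in 4 of 4 (3.55), amnion and trophectoderm genes in 8 of 9 with 0 lower (1.44, 1.08 to 6.60), and primed genes in 8 of 11 with 3 lower (2.26). KRT19 was at 0.577 CPM in fibroblasts and 2352 CPM in feeder-free ESCs. Naive genes had 3 higher and 2 lower of 5 (3.94), S phase genes 16 higher of 17 (2.99), and G2 and M phase genes 20 of 20 (2.94), with MKI67 at 3.92 and 44.3 CPM. FGF and ERK targets had 9 higher and 4 lower of 15 (1.03), nuclear oxidative phosphorylation 13 and 0 of 16 (0.96, and 0.62 under TMM), p53 targets 9 and 1 of 14 (0.85), imprinted genes 7 and 3 of 11 (0.77), and primitive streak and mesendoderm 2 and 2 of 4 (0.54).

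Lower lists for feeder-free ESCs over fetal fibroblasts were fibroblast and mesenchyme, lower in 20 of 20 (median -8.12), neuroectoderm in 3 of 4 with 1 higher (-5.46), YAP and actin targets in 11 of 13 with 1 higher (-4.42), and interferon response in 15 of 15 (-4.06). The proteoglycan gene DCN was at 122 CPM in fibroblasts and 0.254 CPM in feeder-free ESCs, and RSAD2 was at 19.6 CPM and 0 UMIs. Unfolded protein and amino acid stress genes were lower in 11 of 13 with 1 higher (-2.47), BMP targets in 9 of 13 with 2 higher (-2.29), Activin and Nodal targets in 3 of 4 with 1 higher (-2.00), WNT targets in 5 of 7 with 2 higher (-1.45), hypoxia targets in 6 of 11 with 4 higher (-1.17), and basement membrane and integrin genes in 10 of 17 with 5 higher (-0.94). ID1 was at 526 CPM in fibroblasts and 178 CPM in feeder-free ESCs. Close to 0 lay cholesterol synthesis, with 2 higher and 5 lower of 18 (-0.24), and BMP ligands, receptors and SMADs, with 5 and 5 of 14 (-0.09). The medians of immediate early and heat shock genes (0.14, 6 higher and 6 lower of 14), glycolysis (0.02, 4 and 3 of 16) and ribosomal protein genes (0.01, 8 and 2 of 82) turned to -0.20, -0.32 and -0.33 under TMM.

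At the level of cells, each thinned to 2000 UMIs with none left out, POU5F1 had a UMI in 67.6% of feeder ESCs (65.0 to 70.0) and 87.4% of feeder-free ESCs (86.0 to 88.7). The fibroblasts, which should lack it, gave 0 of 3209 cells. For cells with a UMI at this depth, 3 counts of the total make 0.0935%, and the exact 95% interval reaches 0.115%. The median depth before thinning was 17419 UMIs in fibroblasts against 29170 and 20851 in the ESC libraries. In the fibroblast-like cluster of feeder ESCs, at a median of 11413 UMIs, 8.98% of cells had a POU5F1 UMI. In pluripotent-like cells the POU5F1 shares were 92.4% (90.2 to 94.3) and 93.8% (92.6 to 94.8). SOX2 had a UMI in 27.8% of feeder ESCs and 40.9% of feeder-free ESCs. NANOG had a UMI in 0 of 1387 feeder ESCs (3 counts make 0.216%, and the exact interval reaches 0.266%) and in 0.0885% of feeder-free ESCs. COL1A1 was seen in 99.3% of fibroblasts, 18.8% of feeder ESCs and 1.37% of feeder-free ESCs; within feeder ESCs it was in 54.6% of fibroblast-like cells and 2.23% of pluripotent-like cells. The BMP target ID1 had a UMI in 51.5% of fibroblasts and in 33.1% and 27.3% of pluripotent-like feeder and feeder-free ESCs.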

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

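Barcodes with at most 100 UMIs hold free RNA. They entered the ratios only in the alternative with free RNA subtracted, and their GATA3 level was also given beside the amnion and trophectoderm genes. In them RN18S, the 18S ribosomal RNA gene, took 14.8% of UMIs in the feeder ESC library. This drew attention because it was above the 9.70% in the somatic control; the feeder-free ESC library had 6.82%. In called cells the share was 0.227% to 0.231% in all 3 libraries. No explanation for the difference was tested.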

How the results depend on the processing

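No paired analysis and no leave-one-out was possible because each group has 1 library. Of the 12 recomputed numbers of cells per library, all 12 lay within 1.5 times the main number. The limit of 10% mitochondrial UMIs moved nothing, because the files hold 0 mitochondrial UMIs. Of list medians recomputed under the alternatives, 361 of 376 for feeder-free ESCs over feeder ESCs, 365 of 377 for feeder ESCs over fetal fibroblasts and 343 of 348 for feeder-free ESCs over fetal fibroblasts stayed within the interval of the median (for short lists, the range of the members). Of 1100 recomputed ratios of single named genes, 769 stayed within their counting intervals, 329 moved outside them and 2 reversed; these cover the markers and the 12 highest and lowest ratios, not the other list members. Among the latter, KLF4 (-0.79), JUN (-1.40) and BAX (-1.10) turned to 1.20, 1.81 and 0.44 in pluripotent-like clusters between the ESC libraries. Between the ESC libraries, 5 genes with main ratios under 1.5-fold crossed 0: POU5F1 (-0.11 to 0.39), SALL4 (-0.50 to 0.11), ID1 (-0.12 to 0.37), ID3 (-0.01 to 0.35) and MKI67 (-0.59 to 0.02). Leaving out the fibroblast-like cluster, keeping pluripotent-like clusters alone and keeping cells of at least 15000 UMIs were chosen after seeing the data. The cause was not tested for any of the shifts below, except where the wording says so.

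Between the ESC libraries, the share of measured genes at least 1.5-fold higher in feeder-free ESCs was 9.74% and became 17.1% with the mean of each cell's CPM and 16.7% after thinning to 2000 UMIs; both settings raise the weight of the shallow fibroblast-like cells. Under the mean of cell CPM, list medians for feeder-free ESCs over feeder ESCs became 0.39 for core pluripotency, 0.94 for basement membrane and integrins, 0.24 for G2 and M phase and 0.059 for S phase, which reversed. After thinning they became 0.33, 1.06, 0.26 and 0.028 in the same order, S phase again reversed, and -0.50 for unfolded protein and amino acid stress. With no filter on low values, the neuroectoderm median became -2.12, as more genes near the floor entered.

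Without the fibroblast-like cluster, the medians for feeder-free ESCs over feeder ESCs became -1.04 for fibroblast and mesenchyme and -0.44 for S phase. With pluripotent-like clusters alone they became 0.10 for fibroblast and mesenchyme, which reversed, -0.43 for S phase and -0.26 for cholesterol synthesis. CRABP1 (0.67) and CRYAB (0.93) also reversed there; in feeder ESCs both had their highest levels in the cluster that this setting removes.

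For feeder ESCs over fetal fibroblasts, TMM moved the medians to -0.83 for glycolysis, 0.15 for nuclear oxidative phosphorylation, 2.50 for G2 and M phase and -0.51 for ribosomal protein genes. TMM lowers all ratios of this comparison alike, by its construction. Thinning gave 7.03 for core pluripotency, where the floor of 3 counts weighs more at the lower depth, and 3.34 for endoderm. Endoderm, with 3 members, became 3.32 with totals without ribosomal genes, 2.72 with no filter and 3.28 with pluripotent-like clusters alone. In those clusters Activin and Nodal targets became -1.14 and fibroblast and mesenchyme -7.60; without the fibroblast-like cluster the latter was -6.22. For feeder-free ESCs over fetal fibroblasts, TMM gave 0.62 for nuclear oxidative phosphorylation and -0.33 for ribosomal protein genes, thinning 7.57 for core pluripotency, no filter 2.75 for endoderm, and pluripotent-like clusters alone 1.03 for amnion and trophectoderm.

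Of 40 recomputed class shares, 28 moved outside their intervals. The pluripotent-like share of feeder ESCs was 43.8% at resolution 0.3, 63.7% at resolution 1, 44.2% with 1000 variable genes, 63.7% with cell cycle lists left out and 64.6% with called doublets left out; the unnamed share was 26.5%, 5.19%, 26.1%, 0% and 2.91% in the same order. An endoderm-like class, absent from the main clusters, held 2.74% of feeder ESCs at resolution 1, 4.33% with cell cycle lists left out and 2.55% with doublets left out. The neuroectoderm-like share of feeder ESCs was 0% at resolution 0.3, at resolution 1, with 1000 variable genes and with doublets left out. In feeder-free ESCs the pluripotent-like share was 80.6% at resolution 0.3, 71.8% at resolution 1, 71.0% with 1000 variable genes, 80.1% without cycle lists and 82.3% without doublets. The amnion or trophectoderm-like share was 19.4% at resolution 0.3, 18.9% with 1000 variable genes, 17.5% without cycle lists and 15.5% without doublets, and the unnamed share 0% at resolution 0.3, 14.2% at resolution 1 and 10.1% with 1000 variable genes. The fibroblast-like share of fibroblasts was 67.4% with 1000 variable genes and 63.4% without cycle lists. The fibroblast-like share of feeder ESCs, 28.4% to 29.99%, stayed within its interval in every clustering setting tried. Class shares were not recomputed under other cell calls.

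Shares of cells with a UMI follow the depth to which cells are thinned. At 1000 UMIs, 5000 UMIs and unthinned, POU5F1 was seen in 53.4%, 76.7% and 82.7% of feeder ESCs and 70.8%, 96.4% and 98.8% of feeder-free ESCs. SOX2 was seen in 14.0%, 48.1% and 69.7%, and in 22.3%, 67.7% and 92.8%. COL1A1 was seen in 11.8%, 28.8% and 51.6% of feeder ESCs, 0.796%, 3.85% and 14.6% of feeder-free ESCs, and 96.6%, 99.97% and 99.9% of fibroblasts. Unthinned, NANOG was seen in 0.505% of feeder and 1.11% of feeder-free ESCs, and POU5F1 in 0.280% of fibroblasts.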

Other observations

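The tests of missing genes for another species, of the primed genes without the fibroblast-like cluster, of the amnion genes in pluripotent-like clusters alone (with and without feeder-free clusters 4 and 6, and with 5% taken off) and of cells or free RNA as the source of TFAP2C, KRT7, KRT19 and GABRP were chosen after the result was seen; the other tests were set down before it.

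Within feeder-free ESCs, cluster 4 (408 cells, 18.1%) kept POU5F1 at 1437 CPM, as in the remaining pluripotent-like clusters (1398 to 1690 CPM), but carried GABRP at 66.8 CPM and GATA6 at 42.9 CPM against 26.3 and 19.1 CPM in the rest of the library, with SLITRK6 at 70.9 against 9.39 CPM and CXCL13 at 537 against 125 CPM. In the amnion or trophectoderm-like cluster, POU5F1 was at 591 CPM and SOX2 at 94.3 CPM, with the histamine-forming enzyme HDC at 144 against 2.73 CPM and the imprinted gene MEST at 230 against 13.6 CPM. The 52 unnamed cells had POU5F1 at 139.5 CPM, with KRT7 at 180.0 CPM, ISL1 at 22.4 CPM, the mesenchymal and epithelial regulator NR2F2 at 135 CPM against 1.23 CPM, and FGF8 at 53.3 against 1.55 CPM. The amnion or trophectoderm markers GATA3, TFAP2A and WNT6 were also at least 2-fold above the rest of the library in these 52 cells.

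In feeder ESCs, unnamed cluster 3 (216 cells, 15.6%) combined POU5F1 at 1667 CPM with genes of the Nodal response and of endoderm: FOXA2 was at 37.9 against 2.19 CPM, GSC at 23.2 against 2.01 CPM, SMAD7 at 94.2 against 24.6 CPM and APOA1 at 165 against 30.4 CPM. The 31 cells named neuroectoderm-like, a class at 0% in 4 of 5 other clustering settings, carried PAX6 at 24.9 CPM, SIX3 at 28.8 CPM, LHX5 at 61.5 CPM and the retinoic acid hydroxylase CYP26A1 at 130 CPM. Among the fibroblasts, cluster 7 (50 cells, 1.56%) carried interferon genes, with IFIT1 at 564 against 38.2 CPM and RSAD2 at 444 against 13.4 CPM, while cluster 4 (513 cells, 16.0%) carried CTSK at 281 against 27.9 CPM and STMN2 at 118 against 2.87 CPM. All of these genes were picked because they set the clusters apart.

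A fibroblast-like cluster made up 29.7% of the cells of the feeder ESC library. Pig fibroblasts like the control are argued against: of 495 genes at 200 CPM or more in all clusters of the control library, 21.4% lay under 10% of their lowest such level here, COL1A2 and TAGLN among them. Cells of another species whose reads map to the pig genome in part are a possible explanation. Of genes at 50 CPM or more in all other ESC clusters, 19.7% were nearly missing here against at most 3.22% in the clusters of the control library. Of 82 genes with ribosomal protein symbols, only 4 were nearly missing (RPS15A, RPS19BP1, RPL7L1 and RPL29). The same count with the control library as reference gave 25.8% here against at most 8.64% in the other ESC clusters. A further 30 genes at 100 CPM or more here, such as RPL10L at 582 and MCTS1 at 287 CPM, stayed under 10 CPM in all clusters of the other libraries. Feeder cells are a candidate source, as a hypothesis: the labels do not give their species, and the SSEA4 sort, if it was applied to this suspension, was meant to remove them. No other biological explanation was tested.

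Amnion and trophectoderm genes were higher in feeder-free ESCs. Most cells of clusters 4 and 6 (355 of 408 and 67 of 90) grouped with 295 of the 298 cells of the amnion or trophectoderm-like cluster in joint clustering. Over the 9 members measured in all cells, the median was 1.66 in pluripotent-like clusters and 1.30 without clusters 4 and 6. With 5% of the amnion or trophectoderm-like level taken off, these became -0.12 and -0.17. That subtraction cannot decide the question. GATA2, GATA3, TFAP2A, WNT6 and HAND1 stood under 5% of that level, so it had to set them to the floor. For the list as a whole, the cells of the amnion or trophectoderm-like cluster with some of their RNA in other cells stay open as the source. This source is argued against for TFAP2C, KRT7 and KRT19, whose excess over feeder ESCs was at least 12.4% of that cluster's level with or without clusters 4 and 6, although KRT7 then stayed under 1.5-fold with 5% taken off; it stays open for GABRP, at 20.3% with them and 3.90% without. A spread of 11.6 times between the highest and lowest member argues against free RNA in equal parts, but rests on HAND1 (0.406%, 5 UMIs). For GATA2, GATA3, TFAP2A and WNT6, at 2.55% to 4.72%, free RNA or cells at the border of the clusters therefore stay open. Their excess over feeder ESCs was 1.48% to 4.58% of that cluster's level, and -0.09% to 2.03% without clusters 4 and 6. It was thus not spread evenly over the pluripotent-like clusters. A biological difference may remain for TFAP2C, KRT7 and KRT19 as a hypothesis, and the loss of feeders, LDN-193189 and any sort cannot be told apart by this design.

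Primed pluripotency genes were lower in feeder-free ESCs. The fibroblast-like cluster of feeder ESCs is argued against, since the median stayed at -0.97 without it. With pluripotent-like clusters alone and every cell thinned to 2000 UMIs, the median was -0.96. This argues against a larger weight of deep cells in the sums. Random thinning keeps the expected gene shares of each cell, so it cannot decide on other effects of depth. A difference between the cultures may explain it, as a hypothesis, but the loss of feeders and LDN-193189 are confounded, 1 library per group leaves library effects untested, and passage number was not tested.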
